A study of Mus musculus with 8 samples.

How the data were processed

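Methylated DNA was enriched from mouse liver by MCAM, methylated CpG island amplification read on microarrays, in which genomic DNA is digested with restriction enzymes that differ in their sensitivity to methylation, ligated to adaptors and amplified, so that a brighter probe marks a more methylated fragment. The labels give C57BL6/J liver in late gestation (E17.5) and at weaning age (P21), with 2 biological replicates of each age. Per the labels, E17.5 DNA carried Cy3 and P21 DNA carried Cy5 on every array. No dye swap was made on the arrays analysed here, so age and dye cannot be told apart. Each replicate was hybridised to a pair of array designs. The labels divide these between chromosomes 10 and 11, whereas the probe names in the files place the division within chromosome 9. The 2 ages of one replicate share an array, and their deposited scanner files hold identical tables, from which the Cy3 columns were read for E17.5 and the Cy5 columns for P21. The 4 arrays are therefore 2 independent comparisons per locus, and their number limits the precision.

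Per the file headers, the authors extracted intensity values with Agilent Feature Extraction 9.1.1.1 (1 array) and 9.1.3.1 (the other arrays); the submitters' processing notes name 9.1.1.1. Per the file headers, the processed signals are background-subtracted intensity values with a linear dye normalization, 1 factor per channel. The deposited log10 ratio of red over green, per the file headers, was read to check the direction of the ratio. Per the file headers, the flags for outlier, saturated and well-above-background spots come from the same software. The authors' deposited series table holds the same intensity values of each sample's own dye channel, on a linear scale and uncentred: 100% of its values lay within 0.6% of the scanner values in all 8 samples, so neither its scale, centring nor direction stays unknown. Its medians for E17.5 were 460 and 308 on the first array design and 341 and 275 on the second, and for P21 454 and 312, then 330.2 and 267. The genome build of the probe coordinates is not given in the sources used here. Coordinates are printed as the probe names give them, and the position of a probe within its gene is not known.

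Log2 ratios of P21 over E17.5 were taken from the processed signals and centred on each array's median, with no loess or quantile step, because many fragments may shift one way in an enrichment assay. Before centring, the array medians lay between -0.0021 and 0.025. Controls, outlier spots and probes not well above background in at least 1 channel on every array were left out. This kept 29838 of 41545 probes on the first array design and 29678 of 41577 on the second. Probes no more than 500 bp apart were joined into regions, and a region's value is the mean of its tested probes. Gene names are those in the files: 11571 names are current symbols, 3916 were updated from older symbols through the RefSeq gene table for GRCm38.p6, 434 were not matched, 1151 are hyphen-joined pairs of genes kept as given, and 2284 give coordinates only.

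The test was limma 3.58.1 in R 4.3.3 (intercept against 0, empirical Bayes, Benjamini-Hochberg adjustment), with data.table (version 1.17.8); figures were drawn with matplotlib 3.10.9. A probe or region was called at an adjusted p under 0.05, a mean log2 ratio of at least 1 in size and the same sign on both arrays. The array is a block by construction, since both ages share it: deviations of the 2 channels of an array from their age means correlated at 0.680 across 17617 regions. Gene lists were tested with camera (preset correlation 0.01), with fry, and by the percentile of their median among 10000 random lists matched on signal. The ratio, test, thresholds, 17 gene lists and naming rule were fixed before the data were examined. The rule names the 12 called regions a side with the largest ratios, among regions with a gene name and at least 2 probes that all have the region's sign. Where none was called, it names the 5 regions of at least 2 probes with the largest ratios on that side. The condition on sign was carried over to these 5, which left out Bdh1, with 1 of its 6 probes below 0; without that condition Bdh1 would stand in place of Def6. It also names the 2 members of each list with the largest ratio in size, and H19, Igf2, Igf2r, Afp, Alb, Hnf4a and Gata1, as not passing where they did not. H19 had no probe on these arrays.

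Several choices were made after the data were seen. A first exploratory fit joined tested probes only into regions; the regions used here join all probes of the array, as a reading of the fixed definition that does not move with the filter. Both readings gave 0 called regions. The counts of regions over 2-fold on both arrays, the fits on autosomes only and the rank product were added after the fit on all regions had called 0. The yardstick for the counts over 2-fold on both arrays is the number of regions over 2-fold on both with opposite signs.

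The procedure was tested on simulated data for the 17617 regions, with noise drawn from real regions of like signal and 50 regions changed at each size. limma called 0% of regions changed by log2 1, 18% at log2 2, 48% at log2 3 and 44% at log2 4, and 0 unchanged regions. The rank product called 23 regions in simulated data with no change at all, and its calls are given only as a count. The simulated noise was heavier than that of the arrays. With no change, 34 regions were over 2-fold on both in opposite directions, against 7 in the data. The shares detected and the false calls therefore hold for that noise and may not carry over to the arrays. A list of 30 genes shifted by log2 0.5 passed camera, with 0 of the other lists passing. The list median of largest size in the data was -0.16, so this says nothing of shifts of the size seen. Alternatives covered normalization, background, filters, thresholds, variance moderation, the block, region definition and replicates. A correction for probe GC content was not run, since no probe sequences were used here. The normexp alternative started from the scanner's mean signals, with an offset of 50 and without the linear dye factors. It therefore changed the dye normalization and the scale of dim signals along with the background. The labels call the replicates biological and do not say how many animals each holds. The p-values rest on the spread between the 2 within-array ratios. That spread is moderated towards that of the other regions, with a prior of 2.08 degrees of freedom over all regions.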

Results

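Liver changes from a blood-forming organ before birth to a metabolic organ by weaning, and the series asked which loci differ in DNA methylation between E17.5 and P21 in C57BL6/J mice. Methylation-enriched DNA of both ages was compared on 4 arrays with both dyes, 2 biological replicates for each of 2 array designs. E17.5 carried Cy3 and P21 carried Cy5 on all 4, so age and dye cannot be told apart in any value given here. Between 67.0% and 75.9% of probes read well above background in E17.5 and between 71.9% and 77.1% in P21. The tested probes numbered 59516, in 17617 regions with a median of 3 probes, of which 14183 held at least 2. The SD of the log2 ratios was 0.30 and 0.40 on the replicate 1 arrays and 0.45 and 0.60 on the replicate 2 arrays.

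No region passed the test for a difference between the ages over all regions. The region with the largest positive ratio lay in Nrbp2, which encodes a nuclear receptor binding protein. Its 7 probes, on chromosome 15 from 76138436 to 76139542, averaged a log2 ratio of 4.04 ± 0.03 (SD, n = 2), 16.4-fold more signal in P21, with an adjusted p of 0.140 over all regions and 0.0616 over regions of at least 2 probes. Nrbp2 was called in 6 of 19 alternative limma fits over regions of at least 2 probes and in 3 of 20 over all regions, with a log2 ratio between 3.72 and 4.50 over these alternatives. Among the 6 was the fit on autosomes, added after the data were seen (adjusted p = 0.0328). A 1.5-fold or no fold minimum and a threshold of 0.01 are among the alternatives and could add no call. Without the array as a block, Nrbp2 had an adjusted p of 1.00 in both. A region in Pbld1, on chromosome 10 from 63026860 to 63027721, had 5.75-fold less signal in P21, with a log2 ratio of -2.52 ± 0.03 over 4 probes (SD, n = 2) and an adjusted p of 0.269. With normexp background correction the ratio of Pbld1 was -1.57, and there it was called (adjusted p = 0.0273).

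limma called 0 of 17617 regions (lowest adjusted p 0.140), 0 of 14183 regions of at least 2 probes (lowest 0.0616) and 0 of 59516 probes (lowest 0.382). At an unadjusted p under 0.05 there were 2077 regions, 902 higher and 1175 lower in P21, against 880.85 that chance would give, 1631 regions of at least 2 probes, and 6936 probes. The rank product called 23 regions, and also 23 in simulated data with no change, and no gene is named from it. The simulated noise was heavier than that of the arrays, so the equal counts cannot say whether the real calls are noise. With that heavier noise limma called 18% of regions changed by log2 2 and 44% of those changed by log2 4. With normexp background correction in place of the processed signals, 61 regions were called, 49 higher and 12 lower. In that setting the ratio followed the signal closely (rho 0.864 across probes, which are not independent, against 0.0534 with the processed signals), and loess after normexp left 2 calls, Nrbp2 and Bdh1. Of the genes named here, Nrbp2, Bmp4, Arhgef40, Def6, Pbld1, Bdh1, Onecut1, Eng, Csf1r, Cebpe, Cox4i2, P2rx7, Aqp6 and 1 region of Sigirr were called with normexp.

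Among the other regions named by the fixed rule as not passing, Bmp4, a signalling ligand of the TGF-beta family, had a log2 ratio of 3.05 ± 0.99 over 2 probes. Arhgef40 stood at 2.57 ± 0.54 over 2 probes and Def6, a signalling protein of lymphocytes, at 1.72 ± 0.34 over 5 probes (2.40 with normexp; SD, n = 2 throughout). The other regions under the rule were on the sex chromosomes and rested on the replicate 2 array. Rbmy1a1, a Y-linked gene of male germ cells, had a log2 ratio of 5.81 on the replicate 2 array and -0.23 on the replicate 1 array. The X-linked regions of Dnaaf6b, Fam3a, Ap1s2 and Diaph2 stood at -6.26, -5.49, -5.38 and -4.80 on the replicate 2 array. On the replicate 1 array they stood at -0.07, -0.47, -0.14 and -0.33. Their means of -3.17, -2.98, -2.76 and -2.57 were -2.51, -2.21, -2.08 and -1.91 with normexp.

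**Figure D1:**
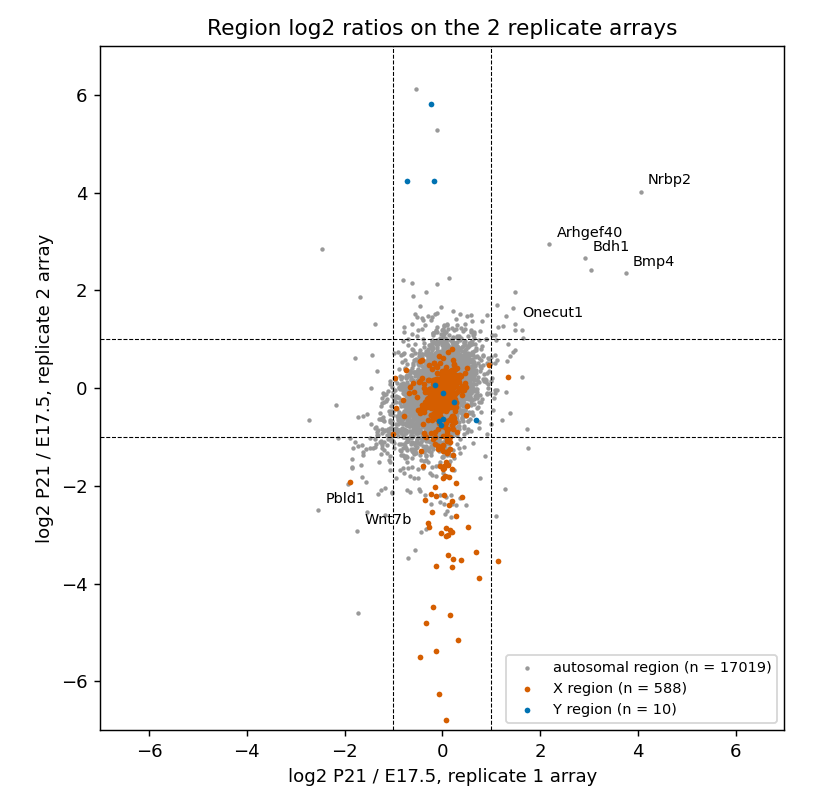
Log2 ratio of P21 over E17.5 per region on the replicate 1 array (x axis) and the replicate 2 array (y axis), 1 point per region, with dashed lines at 2-fold. Nrbp2, Arhgef40, Bdh1 and Bmp4 lie far out at the upper right, and X regions in orange extend downwards on the replicate 2 array only, apart from 1 region over 2-fold lower on both.

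A set of 69 regions differed by 2-fold or more in one direction on both arrays, 17 higher and 52 lower in P21, against 7 with opposite directions. In simulated data with no change, 33 regions differed by that much in one direction on both arrays and 34 in opposite directions. With 34 opposite there and 7 on the arrays, the simulated noise was the heavier. The 33 is therefore no estimate of how many of the 69 are noise. On autosomes with at least 2 probes the counts were 13 higher, 31 lower and 1 opposite. This description was added after the test had called 0 regions, and the genes named from it in this paragraph were chosen after their values were seen. Higher in P21 on both arrays were Bdh1, a mitochondrial enzyme of ketone body metabolism (log2 ratio 2.80 ± 0.18, 6 probes on chromosome 16), and Onecut1, a hepatocyte transcription factor (1.40 ± 0.13, 6 probes on chromosome 9). P2rx7, an ATP-gated ion channel (1.41 ± 0.41), Aqp6, a water channel (1.40 ± 0.12), and Cox4i2, a cytochrome oxidase subunit (1.55 ± 0.14), stood higher as well. Lower in P21 on both arrays were Vps25, of the endosomal sorting machinery (-1.73 ± 0.16; -0.65 with normexp), Sult5a1, a sulfotransferase (-1.40 ± 0.35), and Alas1, the rate-limiting enzyme of haem synthesis in liver (-1.20 ± 0.04; -0.70 with normexp; SD, n = 2 throughout). Sigirr, a negative regulator of interleukin receptor signalling, and Slc38a4, an imprinted amino acid transporter, each had a pair of such regions on the lower side. None of these passed the test, with adjusted p between 0.269 and 0.359.

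The split between directions depended on the filter on dim probes and on the use of normexp, which also left out the linear dye factors. On autosomes the processed signals gave 17 higher and 51 lower, normexp gave 26 higher and 4 lower, and normexp followed by loess gave 11 higher and 15 lower. With no filter on dim probes the processed signals gave 17 higher and 23 lower. The region definition moved the counts but hardly the split: over all chromosomes, a gap of 1000 bp between probes of a region gave 13 higher and 33 lower, and a gap of 200 bp gave 50 higher and 163 lower. The 2-fold lower regions were spread over signal levels, with 17 at the lowest of 3 equal classes of mean signal, 9 at the middle and 26 at the highest, whereas 14 of the 17 higher regions were at the highest.

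**Figure D2:**
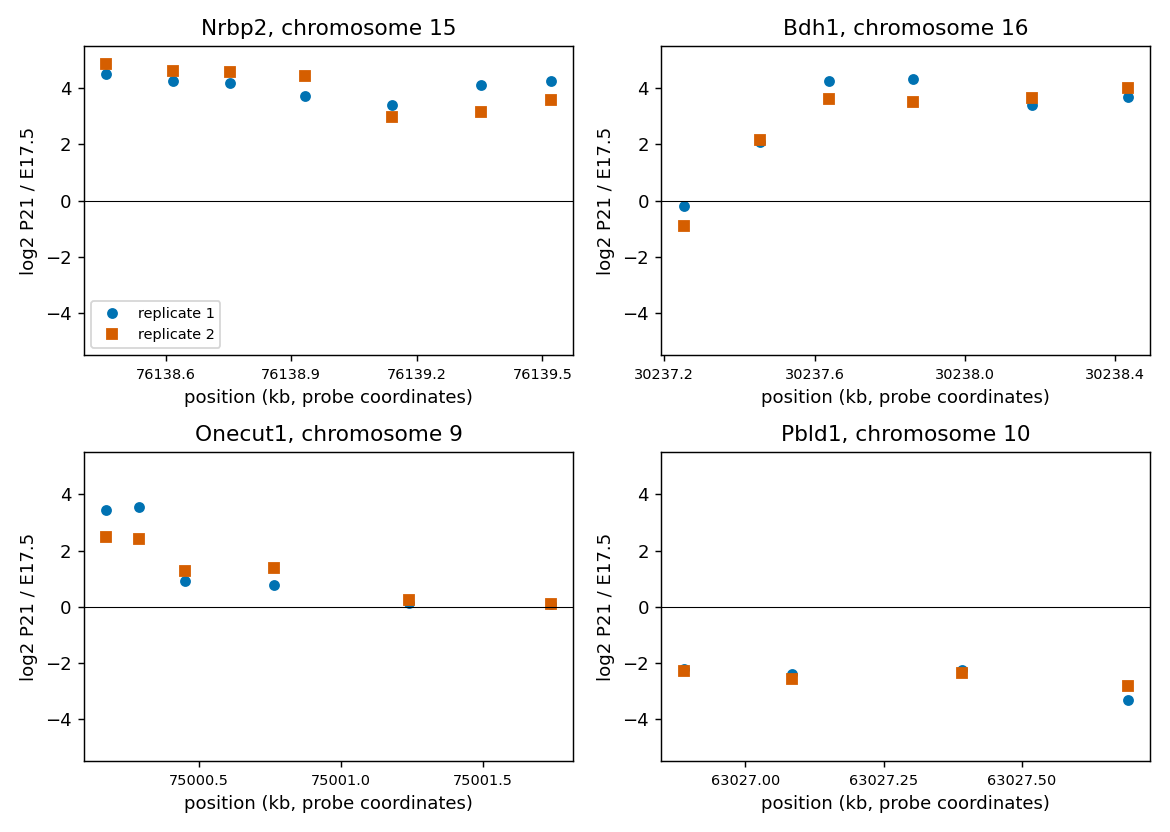
Log2 ratio of P21 over E17.5 per tested probe against probe position in kb, for the regions in Nrbp2, Bdh1, Onecut1 and Pbld1, with replicate 1 as circles and replicate 2 as squares. All 7 probes of Nrbp2 lie between 2.97 and 4.84 on both arrays, and those of Onecut1 are highest at the left end, up to 3.56, and 0.09 at the right end.

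Of the 17 fixed gene lists, 0 passed camera (lowest adjusted p 0.399; 0.774 with an estimated correlation) or fry (lowest adjusted p 0.243), and 0 genes of any list were called over all regions. Adjusted over the list alone, 1 gene passed in each of 4 lists, out of 17 lists examined. These were Onecut1 (adjusted p = 0.0220), Eng, an endothelial co-receptor (1.34 ± 0.20 over 3 probes, 0.0235), Slc38a4 (-1.19 ± 0.12 over 2 probes, 0.0322; -0.47 with normexp) and Smad2, a TGF-beta signal transducer (-1.73 ± 0.13 over 1 probe, 0.0160; SD, n = 2). Over all regions the adjusted p of each was 0.269. The percentiles of list medians below are descriptions, not adjusted over the lists.

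The fetal liver and oncofetal list had a median log2 ratio of -0.16 over 17 measured genes, at the 0.05 percentile of random lists, with 9 genes lower and 2 higher on both arrays. The list medians on the single arrays were -0.04 and -0.09. Its median was 0.02 with normexp and -0.04 with normexp and loess, and camera gave an adjusted p of 0.399. Its members with the largest ratios were Gpc3, an X-linked glypican (-0.73 ± 1.30; 0.19 on replicate 1 and -1.65 on replicate 2; -0.26 with normexp), and Igf2, a fetal growth factor (0.68 ± 0.35 over 3 probes, adjusted p = 0.386; 0.37 with normexp). Germline genes had a median of -0.13 over 21 genes, at the 0.18 percentile, below 0 under all 4 other scalings tried but smaller, -0.06 with normexp and -0.04 with normexp and loess. The median was -0.05 on replicate 1 and -0.13 on replicate 2, and 3 of the genes are on the sex chromosomes, without which these medians were -0.05 and -0.08. They were led by Tdrd1 (-0.94 ± 0.19; -0.37 with normexp) and the X-linked Tex11 (-0.67 ± 0.45; -0.26 with normexp), both of germ cell development. The other homeobox and patterning factors had a median of -0.05 over 80 genes, at the 0.32 percentile, with 37 genes lower and 15 higher on both arrays, and 0.01 with normexp. It was -0.03 on replicate 1 and -0.06 on replicate 2. Bmp4 and the X-linked Sox3 (-1.56 ± 3.27; 0.75 on replicate 1 and -3.88 on replicate 2) led them. Stellate cell and fibroblast genes had a median of -0.09 over 20 genes, at the 1.96 percentile, which was -0.05 with normexp and 0.00 with normexp and loess. It rested mostly on replicate 2, with a median of -0.19 there and -0.03 on replicate 1. Wt1 stood at -0.33 ± 0.15 (-0.12 with normexp) and Twist2 at -0.38 ± 0.43, the latter 0.033 with normexp.

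Liver transcription factors and nuclear receptors had a median of 0.04 over 45 genes, at the 97.87 percentile, above 0 under all 4 other scalings tried (0.05 with normexp and 0.02 with normexp and loess), with 22 genes higher and 9 lower on both arrays. After Onecut1, Pparg had the largest ratio (0.53 ± 0.12; -0.19 with normexp). Erythroid genes had a median of 0.05 over 34 genes, at the 96.51 percentile, and -0.07 with normexp; Dmtn stood at -1.39 ± 0.64 (-0.59 with normexp) and Aqp1 at -0.86 ± 0.48 (-0.46 with normexp), against the sign of the median. Kupffer cell and macrophage genes had a median of 0.07 over 12 genes (93.99 percentile; -0.03 with normexp), with Csf1r at 0.89 ± 0.59 and Timd4 at -0.61 ± 0.39, which were 1.31 and -0.40 with normexp. Its medians on replicates 1 and 2 were 0.03 and 0.08. Other blood cell genes had a median of 0.02 over 40 genes (83.01 percentile), with Cebpe, a granulocyte factor, at 0.80 ± 0.00 after Csf1r, which is in this list too. Endothelial genes had a median of 0.02 over 20 genes (73.07 percentile; -0.02 with normexp), with Eng above and Sox17 at -0.45 ± 0.36.

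The mature hepatocyte list had a median of 0.01 and a mean of -0.04 over 70 genes, while camera pointed up (77.62 percentile; -0.05 as its median with normexp). Trf, the transferrin gene, stood at -1.08 ± 0.32 (-0.64 with normexp) and Hpd, of tyrosine breakdown, at -0.97 ± 0.47 (-0.82 with normexp), neither passing. Imprinted genes had a median of -0.01 over 39 genes (36.01 percentile; 0.02 with normexp and 0.01 with normexp and loess), with Slc38a4 at -1.29 ± 0.32 in its other region and Zrsr1 at -0.80 ± 0.23, which were -0.44 and -0.27 with normexp. Hox genes had a median of -0.01 over 36 genes (35.24 percentile; 0.01 with loess, and above 0 with no centring and with normexp and loess), while camera pointed up, with Hoxb6 at -1.22 ± 1.84 (-0.53 with normexp; 0.09 on replicate 1 and -2.52 on replicate 2) and Hoxa9 at -0.58 ± 0.14. Cell cycle genes had a median of -0.05 over 32 genes (5.66 percentile; 0.00 with normexp), with Foxm1 at 0.61 ± 0.27 and Rb1 at -0.55 ± 0.52, which were 0.88 and -0.16 with normexp. DNA methylation machinery genes had a median of -0.05 over 15 genes (14.26 percentile; -0.06 with normexp and -0.01 with normexp and loess), with Mbd2 at -0.57 ± 0.87 (0.05 on replicate 1 and -1.18 on replicate 2; -0.10 with normexp) and Trim28 at -0.51 ± 0.27. Cholangiocyte genes had a median of -0.01 and a mean of 0.00 over 14 genes (40.3 percentile), while camera pointed up and the median was 0.02 with normexp, with Sox9 at -0.18 ± 0.13 and Cftr at 0.16 ± 0.18 (0.10 with normexp). The growth factor and mTOR list had a median of -0.03 over 33 genes (14.69 percentile; 0.03 with normexp), led by Igf2 and Igf2r. The Wnt, TGF-beta and Notch list had a median of -0.03 over 59 genes (15.16 percentile; 0.01 with normexp), led by Bmp4 and Wnt7b (-2.33 ± 0.84 over 1 probe, -0.95 with normexp; SD, n = 2 throughout). The medians of the Hox, cholangiocyte and mature hepatocyte lists had opposite signs on the 2 arrays. The values of Hoxb6, Foxm1, Mbd2 and Trim28 rested on 1 probe each.

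Of the genes named in advance, none passed the test, and Igf2 had the largest ratio, as given above. Alb, the gene of serum albumin, stood at -0.14 ± 0.00 over 4 probes. With normexp it stood at -0.26 with an adjusted p of 0.0403, short of the 2-fold minimum and so not called. Afp, the fetal counterpart of Alb, stood at 0.03 ± 0.18 and -0.057 with normexp, over 1 tested probe of 5 on the array. Hnf4a stood at 0.01 ± 0.02, and below 0 with loess (-0.0065) and normexp (-0.072). The erythroid regulator Gata1 stood at 0.02 ± 0.13, and -0.14 with normexp. Igf2r, an imprinted receptor, stood at -0.48 ± 0.79 over 1 probe, with 0.08 on replicate 1, -1.03 on replicate 2 and -0.09 with normexp (SD, n = 2 throughout).

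On the X chromosome 13.4% of 1858 tested probes were lower in P21 by 2-fold or more on the replicate 2 array and 1.40% on the replicate 1 array. The autosomal shares were 3.09% and 1.68%. On the Y chromosome 33.3% of 27 tested probes were higher by 2-fold or more on the replicate 2 array and 3.70% on the replicate 1 array. The median log2 ratio of X probes minus that of autosomal probes was 0.03 on replicate 1 and -0.05 on replicate 2, and for Y probes -0.06 and 0.21. With normexp the Y values were -0.16 and -0.24, so that the sign on replicate 2 turned, and the X values -0.03 and -0.17, with the sign on replicate 1 turned. Autosome medians lay between -0.01 and 0.02. With 2 arrays an exact two-sided test of these values cannot give a p below 0.5.

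**Figure D3:**
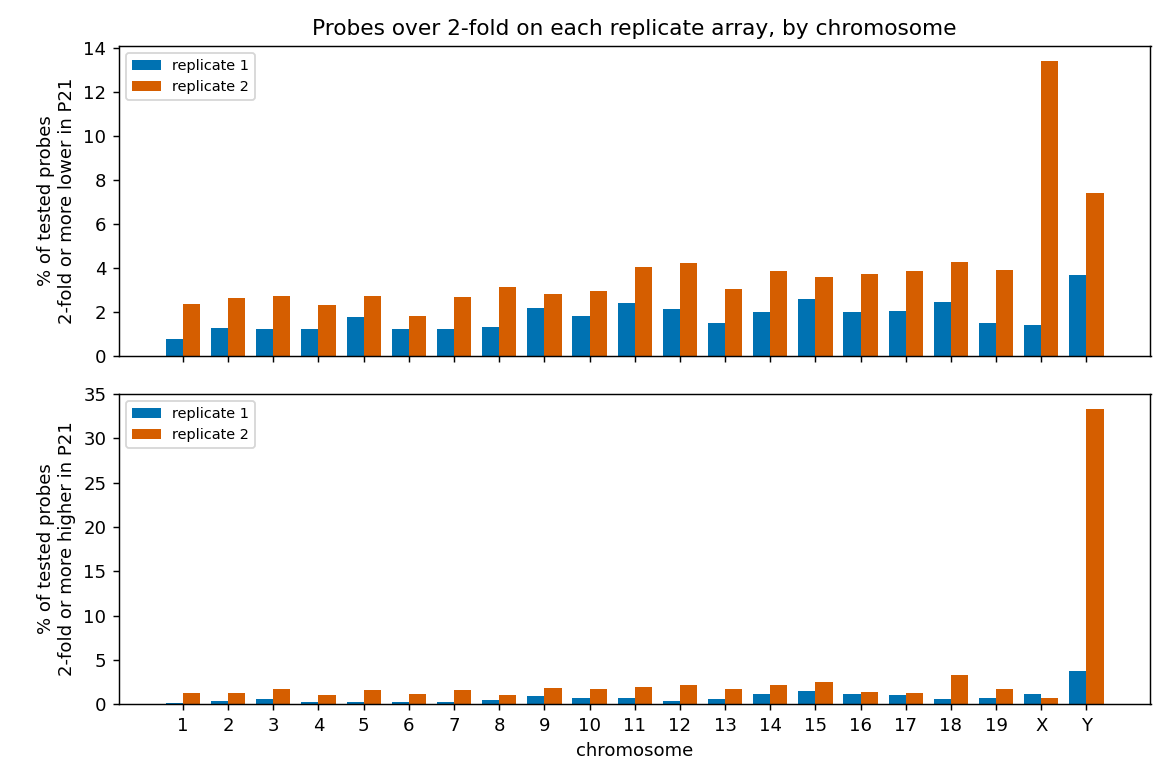
Percent of tested probes lower (top) and higher (bottom) in P21 by 2-fold or more, per chromosome, with replicate 1 in blue and replicate 2 in orange. The X bar in the top panel reaches 13.4% and the Y bar in the bottom panel 33.3% on replicate 2 only.

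Log2 ratios of the 2 replicate arrays correlated at r = 0.337 (Spearman's rho 0.373) across regions and r = 0.337 (rho 0.383) across probes, which are not independent replicates. Across autosomal regions r was 0.399. The sign was shared in 64.1% of regions. Of the 164 regions over 2-fold on replicate 1, 86.0% had the same sign on replicate 2, and of the 418 over 2-fold on replicate 2, 67.9% had the same sign on replicate 1.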

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

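The tests on regions and probes over 2-fold on both arrays, on autosomes only, on regions built from tested probes only, the rank product, the ratios after loess of regions called with normexp, the dim probes of regions without the filter, and the replicate agreement with normexp and loess or with both channels well above background were chosen only after the result was seen. The count of 0 called regions and probes held with loess, the series table (same values), no filter, and trend and robust variance. It also held with the array designs fitted separately, gaps of 1000 or 200 bp, and regions of tested probes only, on autosomes too. Without the array as a block (4 unpaired channels) it was 0. The test gave no adjusted p under 0.05, so a 1.5-fold or no fold minimum or a threshold of 0.01 could call none. For regions of at least 2 probes, 1 region (Nrbp2) was called with no centring, with both channels well above background, at an adjusted p of 0.1, and on autosomes only, and 1 of all regions with 3 or more probes. On autosomes the call rests on the region definition (lowest adjusted p 0.0328 with all array probes, 0.0511 with tested probes only). With the array as a block the adjusted p of Nrbp2 ranged from 0.00444 to 0.379 over all regions and from 0.00336 to 0.175 over those of at least 2 probes. No fixed list passed under any alternative, and none corrected for GC content.

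normexp called 687 probes, 61 regions and 40 regions of at least 2 probes; with loess after it 2 and 2 regions. Its ratio followed signal (rho 0.864), and loess removed that trend (rho -0.00169); the ratios in their direction of the 61 regions went from a median of 1.18 to 0.75, with 19 still over 2-fold and 2 called, while the median SD between arrays went from 0.25 to 0.22. The rank product called 23 regions, and also 23 in simulated data with no change but heavier noise than the arrays. Agreement between replicates (probes, r) was 0.328 with loess, 0.716 with normexp, 0.383 with normexp and loess, 0.417 with no filter, 0.352 with both channels well above background and 0.388 on autosomes. With normexp the X median minus that of autosomes, as a mean of the arrays, was -0.10 (-0.01 with the processed signals) and the Y median minus it -0.20 (0.08 with the processed signals, so its sign turned); the cause was not tested.

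Regions over 2-fold on both arrays numbered 26 higher, 4 lower and 0 opposite with normexp, and 11, 15 and 0 with normexp and loess; 17 and 25 of these were among the 69. The lower count was 23 with no filter: of the 52 lower regions 29 ended, 14 of which gained dim probes, and the array medians that were subtracted went to between -0.05 and -0.13, from between -0.0021 and 0.025. A gap of 1000 bp gave 33 lower and 2 opposite; a gap of 200 bp gave 50 higher, 163 lower and 29 opposite, as it makes more and smaller regions. With 3 or more probes there were 10 higher, 25 lower and 2 opposite, fewer regions being counted. A single array, without replicate 1 or 2 and with no test, gave 43 to 107 regions higher and 121 to 311 lower, and 359 to 958 probes higher and 995 to 2032 lower.

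Of 80 regions named or over 2-fold on both arrays with at least 2 probes, 79 kept their direction with loess, 75 with normexp and 80 with no centring. Reversed were Hnf4a (-0.0065 with loess, -0.072 with normexp), Afp (-0.057), Gata1 (-0.14), Pparg (-0.19) and Twist2 (0.033) with normexp, none called. Only Twist2, the brightest, rose, as the normexp trend runs. Leaving out a replicate leaves 1 array, so it says nothing about the stability of a named region. Signal over background limits E17.5 on the replicate 2 arrays most, where 4.77% and 8.46% of tested probes had a substituted low value, against 1.03% and 3.91% on replicate 1.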

Other observations

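The tests of the X and Y pattern and of background subtraction, the comparison with regions of opposite directions and the share with no filter, were chosen only after the result was seen.

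The regions of X lower and Y higher in P21 appeared on the replicate 2 array, apart from 1 X region lower by 2-fold or more on both. A dimmer array did not account for the X probes: their share lower by 2-fold or more was 3.43 times (95% bootstrap interval 2.90 to 4.02) that of autosomal probes of like signal on the same array. A difference in sex between the ages on that array stays open. Of 30 Y probes well above background in P21 there, 73.3% were so in E17.5 too, against 96.2% on the replicate 1 array. The interval of 54.1% to 87.7% treats these probes of 1 array as independent, which they are not. The share cannot decide the question, since a probe well above background in both ages may still differ in ratio. The 3 regions of Rbmy1a1, chosen after their values were seen, stood at 4.23 to 5.81 on the replicate 2 array and between -0.73 and -0.18 on the replicate 1 array. The labels give no sex.

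The autosomal regions over 2-fold on both arrays numbered 68, against 6 with opposite directions. A dye preference of single probes would leave their neighbours near 0. The 513 autosomal probes over 2-fold on both arrays that had other probes in their region lay in 352 regions, most outside the 68. Those other probes had a median log2 ratio of 0.57 in the same direction (95% bootstrap interval 0.45 to 0.66). This argues against a dye preference of single probes for these probes as a set. For the 44 regions of the 68 with 2 or more probes it cannot decide, since their means were selected as over 2-fold. The 24 regions of 1 probe are not covered. With both channels well above background, 63 regions were over 2-fold on both arrays. This was 42.0 times the number independent arrays give and 10.5 times the 6 with opposite directions. It argues against different signal floors only for channels not well above background. The first yardstick is too low: over autosomal regions, 6 had opposite directions against the 1.31 that independent arrays give. Loss of blood-forming cells between the ages stays open, with the erythroid list at the 96.51 percentile, short of the bound set for it; a dye effect shared by whole fragments, and age itself, stay untested, as every array carried the ages in the same dyes.

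More of these regions were lower than higher in P21, 51 against 17. With both channels well above background the share of lower regions was 73.0% (exact 95% interval 60.3% to 83.4%). This argues against different floors only for channels not well above background. The filter kept 16589 of 17019 autosomal regions, so floors that reach signals above it stay open. The low end of the processed signals was higher in E17.5 on every array, most on the second design of replicate 2 (87.3 against 47.5). A dye effect that changes with signal stays open: loess left a share of 76.5% (64.6% to 85.9%), but had almost no trend to remove, with a rho of 0.0534 between ratio and signal. The way the background was subtracted stays open, as normexp with loess gave 57.7% (36.9% to 76.6%, 26 regions). That setting also had an offset and no linear dye factors, so a change of background alone was not tested. The excess of lower regions may come from any of these steps. With no filter on dim probes the share was 57.5% (40.9% to 73.0%), so the excess also depends on the filter and the centre it sets.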
